A study of Mus musculus with 6 samples.

How the data were processed

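Messenger RNA was measured in 6 libraries of mouse cerebral cortex cells, sorted for GFP after electroporation with GFP and either wild-type or mutant PRPF6 (3 libraries each). Per the labels' protocols, cDNA was made from picogram amounts of RNA with the SMART-Seq low-input kit, sheared, and sequenced as paired ends on an Illumina HiSeq, with all libraries pooled on a single lane. Groups were taken from the treatment in the labels and replicate numbers from the sample titles. In both groups the sample descriptions number replicates 1, 2 and 3 as 1, 4 and 5. The labels do not say what these numbers mark.

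The deposited values are expected counts per gene, not scaled for depth, made with RSEM on the mouse build mm10 per the submitters' processing notes. RSEM divides reads that fit several genes between them, so expected counts need not be whole: 8.15% to 9.15% of the values in a library were not. The RSEM version, the aligner, the gene annotation, the strand setting and any filter are not given in the sources used here. The file holds 24041 genes by symbol, some of them older ones. Without a known strand setting, reads of overlapping and antisense genes cannot be separated. Among the tested genes 2392 had a value that was not whole in at least 1 library, and their counts depend on how RSEM divided shared reads. Amplification from so little RNA without molecular identifiers means that reads are not independent molecules.

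The expected counts were rounded to whole numbers. Genes were filtered with filterByExpr, which left 14451, and libraries were scaled with TMM factors, which lay between 0.972 and 1.02. Differences were tested with edgeR 4.0.16 (robust quasi-likelihood F-test, two-sided, group as the only term) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation was 0.663, and the median standard error of a log2 difference was 0.341. CPM values use the library totals, 45115122 to 60600617 counts, multiplied by the TMM factors, so that 1 count was worth 0.0164 to 0.0228 CPM. Between 14651 and 16373 genes had at least 1 count in a library, and the 10 most abundant genes took 3.53% to 5.14% of the counts. Spearman's rho across genes was 0.931 to 0.961 between libraries of a group and 0.922 to 0.970 between groups, where genes are not independent replicates.

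Before the data were examined, 34 gene lists with 843 entries were fixed for cell types and states of the cortex, the spliceosome, the centrosome, stress pathways, and the other cells a sort could hold. Of these entries 822 were found under their own or an older symbol. Lists with at least 5 tested members, 33 in all, were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 33 lists. Camera with an estimated correlation and fry were run beside it, and edgeR p-values were also adjusted over each list alone. The adjustment over a list alone has no correction across the 33 lists, so members passing it are weak evidence for single genes. Mitochondrially encoded genes were not analysed here. A list score is the mean log2 CPM of a list's tested genes in a library, minus the mean over the 6 libraries. Scores of the groups were compared with a two-sided exact permutation test, whose smallest p for 3 against 3 is 0.10.

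The genes to name were also set before the data were examined. They were Prpf6 and Brsk2, and up to 12 genes per direction past the test, with a mean log2 CPM of at least 1, a proper name and all mutant libraries on one side of all wild-type libraries. Where fewer passed, a direction was filled up to 6 by the smallest unadjusted p. Each list with a call gave up to 4 members past the test or, where none passed, the 2 of smallest unadjusted p, and 6 lists central to the design always gave 2. This named 36 genes. A gene outside the rule is said to have been named after its values were seen.

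Alternatives set in advance were DESeq2 size factors, upper-quartile factors, no low-count filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, no robust estimation, an adjusted p under 0.1, a block for the replicate number, and leaving out each library in turn. Chosen after the data were seen were a fit without both wild-type replicate 3 and mutant replicate 1, and fits with a red blood cell score or a Y-linked score as a covariate. Length and GC trends, removed from each library by loess over genes, were first a test of 1 explanation and later added as an alternative for lists with both values for nearly all members. The alternatives with pseudocounts planned for normalized values did not apply. DESeq2 gave no adjusted p for 11213 genes, which stay out of its counts. Coordinates are those of GENCODE M21 on GRCm38, matched by symbol.

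The steps were tested on simulated data for the comparison of mutant with wild-type PRPF6: 3 simulations of the 14451 genes, each with 200 genes changed. At the spread of these libraries 12% of the genes changed 2-fold and 50% of those changed 4-fold were recovered, and 13 of 203 calls were false. A simulated 1.5-fold rise of the radial glia list was called in 3 of 3 simulations, with 0 calls of other lists. Genes were simulated as independent of each other, whereas the estimated correlation in the real libraries was 0.28 for radial glia and 0.89 for G2 and M phase. The simulations therefore cannot show how often camera with the preset correlation calls a list falsely in these libraries.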

Results

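The libraries measured messenger RNA in mouse cerebral cortex cells that had been electroporated, that is, given plasmid DNA by electric pulses, and then sorted for green fluorescent protein (GFP). One group had received GFP with wild-type PRPF6 (3 libraries) and the other GFP with a mutant PRPF6 (3 libraries). PRPF6 is a protein of the U4/U6.U5 tri-snRNP, the particle that brings catalytic RNAs to the spliceosome. The total expected counts were 47564897, 60600617 and 49484457 in wild-type replicates 1, 2 and 3, and 57475218, 48787926 and 45115122 in mutant replicates 1, 2 and 3. The labels do not say whether the libraries came from separate animals, so every p-value covers only the spread between these libraries, which may be partly technical.

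The design gives a single comparison, mutant against wild-type PRPF6, and asks which transcripts differ between cortical cells given mutant and wild-type PRPF6. No group went without a PRPF6 plasmid, so a rise with mutant PRPF6 cannot be told from a fall with wild-type PRPF6. Prpf6 (chromosome 2, 181591868 to 181655660, plus strand, GRCm38) was at 166, 124 and 132 CPM (counts scaled to a common library total) in wild-type replicates 1, 2 and 3 and at 131, 145 and 125 CPM in mutant replicates 1, 2 and 3. The group means were 141 ± 22.6 CPM (SD, n = 3) with wild-type and 134 ± 10.01 CPM (SD, n = 3) with mutant PRPF6, a log2 difference of −0.073 ± 0.17 (SE; edgeR quasi-likelihood test, adjusted p = 1.00). Without wild-type replicate 1 the sign turned, to 0.067. Both groups received a PRPF6 plasmid whose species the labels do not state, so whether these counts include plasmid transcripts is open. Brsk2 (chromosome 7, 141949751 to 142004247, plus strand), a kinase of neuronal polarity, was at 106 ± 10.7 CPM with wild-type and 118 ± 6.34 CPM with mutant PRPF6 (SD, n = 3 each), a log2 difference of 0.15 ± 0.15 (SE). Counts per gene do not show which exons of Brsk2 or of any other gene were joined.

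In the mutant PRPF6 libraries, gene lists of radial glia, Notch signalling and p53 targets were higher, and lists of neuronal maturation, newborn neurons, regulatory splicing factors, immediate early genes, red blood cells and meningeal fibroblasts were lower. All 28 tested radial glia genes had higher fitted means with mutant PRPF6, with a median log2 difference of 0.57. For p53 targets 22 of 29 were higher (median 0.67), and for neuronal maturation and synapse 23 of 25 were lower (median −0.40). These 9 of 33 lists passed camera with a preset inter-gene correlation of 0.01 (adjusted p under 0.05). With the correlation estimated for each list 0 lists passed, and fry, which tests a list by itself, also passed 0. List scores of the groups overlapped for neuronal maturation and red blood cells (two-sided exact permutation p = 0.20 each). They also overlapped for newborn neurons and meningeal fibroblasts (0.30 each) and immediate early genes (0.40). Of the 10 splits of the libraries into 3 against 3, the real one included, 7 gave at least 9 list calls.

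No single gene among 14451 tested passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (lowest adjusted p = 1.00). At an unadjusted p under 0.05 stood 489 genes, 315 higher and 174 lower with mutant PRPF6. That is a smaller share of the tested genes than the 0.05 expected by chance. With edgeR, other splits of the libraries into 3 against 3 gave 247 to 868 such genes. limma-voom also called 0 genes, with 551 at an unadjusted p under 0.05. DESeq2 called 10 genes, all higher with mutant PRPF6, with 642 at an unadjusted p under 0.05. In 665 genes all 3 mutant libraries lay above all 3 wild-type libraries and in 656 all lay below. Together these were 9.14% of the tested genes, against 10% by chance for 3 libraries against 3.

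Radial glia are the neural stem cells of the developing cortex. Their list had a camera adjusted p of 8.38e-09, and an adjusted p of 0.721 with an estimated correlation. Adjusted over the list alone, with no correction across the 33 lists, 4 of 28 members passed the edgeR test, against 0 adjusted over all genes. Sox9 (chromosome 11, 112782224 to 112787760), a transcription factor of neural stem cells, went from 275 ± 50.3 to 510 ± 89.3 CPM (SD, n = 3 each), a log2 difference of 0.89 ± 0.19 (SE). Sox21, another SOX factor of progenitors, went from 91.4 ± 20.0 to 163 ± 17.1 CPM. The other members past the test over the list alone were Notch1 and Ednrb, an endothelin receptor named after its values were seen (1.41 ± 0.38, SE). That count ran from 0, without wild-type replicate 1 or 2 or mutant replicate 1, to 7 without mutant replicate 2, and was 1 without wild-type replicate 3. The mean list score was −0.28 ± 0.39 with wild-type and 0.28 ± 0.10 with mutant PRPF6 (log2 units around the 6-library mean, SD, n = 3; two-sided exact permutation p = 0.10, the smallest that 3 against 3 allow).

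The Notch signalling list, which shares Hes1, Hes5, Notch1 and Notch2 with the radial glia list, was higher in 15 of 18 members (median log2 difference 0.47, camera adjusted p = 2.85e-05). Its adjusted p was 0.339 with an estimated correlation. Adjusted over the list alone, 3 members passed: Nrarp, Notch1 and, named after its values were seen, Notch3 (1.39 ± 0.37, SE). Nrarp (chromosome 2, 25180758 to 25183339), a Notch target that feeds back on the pathway, went from 110 ± 25.7 to 204 ± 32.3 CPM, and the receptor gene Notch1 from 114 ± 22.9 to 193 ± 25.4 CPM (SD, n = 3 each). Over the list alone 0 members passed without wild-type replicate 3 or without mutant replicate 1, and 1 without wild-type replicate 1 or 2. Wild-type replicate 3 had the lowest radial glia score, −0.69, and the highest red blood cell score, 3.24. Without that library 24 of 28 radial glia genes and 15 of 18 Notch genes were higher, with camera adjusted p of 0.00171 and 0.00458.

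Intermediate progenitors, the dividing daughters of radial glia, gave no list call (12 of 18 members higher, camera adjusted p = 0.104). The list passed without wild-type replicate 1 (adjusted p = 0.00554), mutant replicate 1 (0.0235) or mutant replicate 2 (0.0293), but with an estimated correlation adjusted p in those fits was 0.937, 0.978 and 0.818. The median log2 difference, 0.30, fell to 0.089 without wild-type replicate 3 and to 0.00081 without mutant replicate 3 (9 members higher, 9 lower), and with the red blood cell score as a covariate it was −0.21 (7 higher, 11 lower). Btg2, an antiproliferative gene of neurogenic progenitors, went from 147 ± 22.6 to 234 ± 11.6 CPM (SD, n = 3 each; log2 difference 0.67 ± 0.16, SE). It was the 1 member past the test over the list alone. That count was also 1 without wild-type replicate 2 and 0 without any of the other libraries. Mfng, a glycosyltransferase that modifies Notch receptors, was at 88.2 ± 13.6 and 126 ± 27.3 CPM.

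The list of p53 targets, genes switched on by the tumour suppressor p53 after DNA damage and other stress, had a camera adjusted p of 1.73e-06 (adjusted p = 0.721 with an estimated correlation). Of its 29 members 10 were higher at an unadjusted p under 0.05 and 0 lower. Adjusted over the list alone, 0 passed, and 7 did without mutant replicate 2. Aen (chromosome 7, 78895854 to 78911209), a p53-induced nuclease, went from 51.3 ± 6.07 to 102 ± 30.1 CPM (SD, n = 3 each), a log2 difference of 0.99 ± 0.25 (SE). Btg2 belongs to this list too. The list score was −0.34 ± 0.31 with wild-type and 0.34 ± 0.36 with mutant PRPF6 (SD, n = 3; two-sided exact permutation p = 0.10). The mutant scores were 0.68, −0.04 and 0.37 in replicates 1, 2 and 3.

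Genes of neuronal maturation and the synapse were lower with mutant PRPF6 (camera adjusted p = 1.72e-05, and adjusted p = 0.721 with an estimated correlation). Adjusted over the list alone, 0 of 25 members passed, and 6 did without mutant replicate 2. Snap25 (chromosome 2, 136713453 to 136782428), a SNARE protein of vesicle release, went from 72.7 ± 15.3 to 34.4 ± 11.7 CPM (SD, n = 3 each; log2 difference −1.08 ± 0.30, SE). Syt4, a synaptotagmin, went from 108 ± 15.7 to 56.1 ± 16.4 CPM. The list score was 0.26 ± 0.20 and −0.26 ± 0.38, and the groups overlapped (SD, n = 3; two-sided exact permutation p = 0.20). With each library's red blood cell score as a covariate, added after the data were seen, the list's camera adjusted p was 0.144. The median log2 difference in that fit was −0.091, with 14 members lower and 11 higher.

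Newborn and migrating excitatory neuron genes were lower in 16 of 20 members (median log2 difference −0.57, camera adjusted p = 0.00224, and adjusted p = 0.983 with an estimated correlation). Adjusted over the list alone, 0 members passed, and 3 did without mutant replicate 2. The call was lost without wild-type replicate 1 (adjusted p = 0.244) or mutant replicate 1 (0.126). The median was −0.13 and −0.29 in those fits and −0.99 without mutant replicate 2. Sox11, a transcription factor of young neurons, was at 2142 ± 805 CPM with wild-type and 1351 ± 164 CPM with mutant PRPF6 (SD, n = 3 each), from counts partly shared with other genes. Mapt, which encodes the microtubule protein tau, was at 162 ± 72.5 and 83.5 ± 62.7 CPM. The deep-layer neuron list was lower in 11 of 16 members and missed the threshold (camera adjusted p = 0.0535), but passed without mutant replicate 2 (0.0269). With an estimated correlation it did not pass in that fit either.

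**Figure D1:**
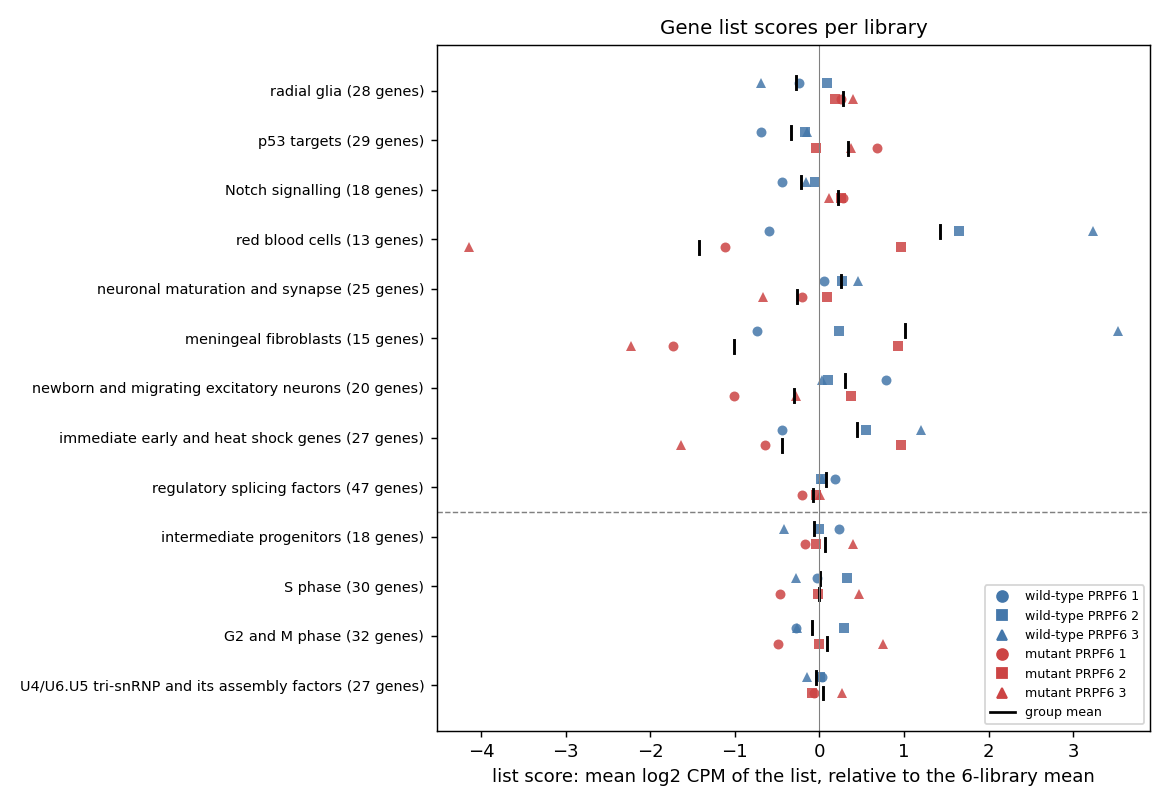
List scores per library: the mean log2 CPM of each list's genes, relative to the mean of the 6 libraries, with blue symbols for wild-type and red for mutant PRPF6, 1 symbol shape per replicate and a black bar at each group mean. The 9 lists above the dashed line passed camera with the preset correlation; radial glia, p53 target and Notch scores of the 3 mutant libraries all lie above those of the 3 wild-type libraries, while red blood cell scores run from −4.14 to 3.24.

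Of the tri-snRNP and its assembly factors, the complex to which PRPF6 belongs, 19 of 27 tested genes were higher and 8 lower, with a median log2 difference of 0.026 (camera adjusted p = 0.386). Without mutant replicate 2 the list passed (adjusted p = 0.0356), though not with an estimated correlation, and without mutant replicate 3 its direction turned (0.456). Snrnp200, the helicase that unwinds U4 from U6, was at 175 ± 20.0 CPM with wild-type and 262 ± 22.8 CPM with mutant PRPF6, and Prpf3, a U4/U6 protein, at 77.2 ± 11.3 and 120 ± 28.8 CPM (SD, n = 3 each). Neither passed over all genes or over the list alone. Regulatory splicing factors were lower in 31 of 47 members (median −0.14, camera adjusted p = 0.0259, and adjusted p = 0.983 with an estimated correlation), with 0 past the test over the list alone. The regulatory list shares Rbfox1 and Rbfox3 with the neuronal maturation list, so the 2 lower lists are not fully separate results. Its other members were not sorted by the cells that express them. A difference in the mix of cells was therefore not separated from a change in splicing regulators. The RNA-binding gene Qk was at 306 ± 19.2 and 487 ± 78.8 CPM, against the direction of its list, and Khdrbs2, a KH-domain splicing regulator, at 31.2 ± 6.37 and 13.8 ± 6.29 CPM. This call was lost without wild-type replicate 1 (adjusted p = 0.396), mutant replicate 1 (0.190) or mutant replicate 2 (0.184), where 1 member passed over the list alone. The median was −0.057 without wild-type replicate 1 and −0.093 without mutant replicate 1, but still −0.14 without mutant replicate 2. With length and GC trends removed from each library the call was lost too (adjusted p = 0.385, score difference −0.041 against −0.15). Other core spliceosome genes were split, 23 higher and 23 lower (camera adjusted p = 0.397).

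Centrosome and centriole genes, which the series title names as its subject, were higher in 21 and lower in 30 of 51 members, with no call (camera adjusted p = 0.397). Without wild-type replicate 3 the list passed as lower (0.0166), though not with an estimated correlation. The direction turned without wild-type replicate 1 or 2 or mutant replicate 1. Akap9, a scaffold of the centrosome, was at 368 ± 60.5 and 288 ± 12.1 CPM, and Pcm1, a scaffold of centriolar satellites, at 185 ± 37.9 and 143 ± 8.14 CPM (SD, n = 3 each, wild-type first). Genes of neuronal migration and cortical malformation were higher in 15 and lower in 20 of 35 members (camera adjusted p = 0.934), with a median log2 difference of −0.043 and a mean of 0.027. Without wild-type replicate 1 or mutant replicate 3 that list's direction turned. Gpr56, an adhesion receptor also called Adgrg1, was at 436 ± 64.7 and 640 ± 84.4 CPM, and Map1b, a microtubule-associated protein gene, at 3344 ± 299 and 2476 ± 435 CPM. No member of either list passed, over all genes or over the list alone.

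**Figure D2:**
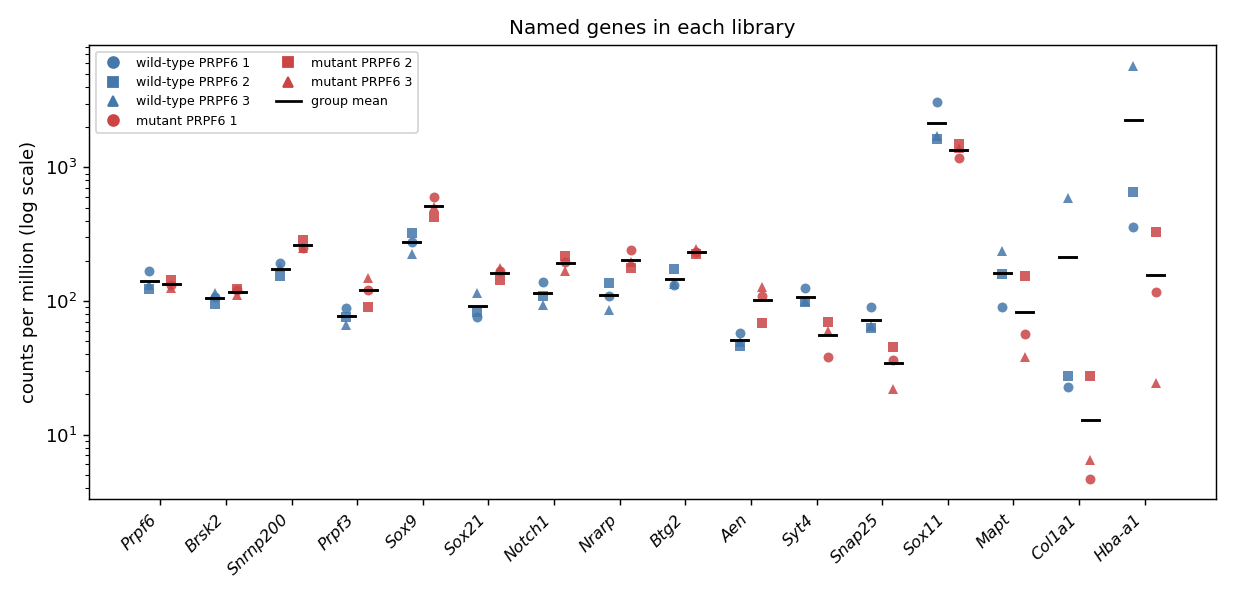
CPM on a log axis for 16 genes in each library, with blue symbols for wild-type and red for mutant PRPF6, 1 symbol shape per replicate and a black bar at each group mean. Sox9 spans 225 to 325 CPM in the wild-type and 424 to 602 CPM in the mutant libraries, Prpf6 overlaps, and Hba-a1 and Col1a1 are highest in wild-type replicate 3.

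Cell cycle lists gave no call. G2 and M phase genes were higher in 30 of 32 members (camera adjusted p = 0.0714) and S phase genes in 16 of 30 (0.864). Both depended on mutant replicate 3, which had the highest G2 and M phase score, 0.75. Without it both lists turned lower, with adjusted p of 0.0758 for G2 and M phase and 0.0166 for S phase. Both passed as higher without mutant replicate 1 (1.56e-07 and 0.00728) or without wild-type replicate 2 (0.000255 and 0.0426), and the G2 and M phase list also without mutant replicate 2 (0.0356). The S phase list turned lower without wild-type replicate 3 as well (0.245). With an estimated correlation neither list passed in any of these fits. That correlation was 0.89 for G2 and M phase and 0.76 for S phase with all libraries.

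Genes of cells outside the neural lineage differed widely between libraries. Red blood cell genes were lower with mutant PRPF6 in all 13 tested members (median log2 difference −2.80, camera adjusted p = 8.72e-06, and adjusted p = 0.766 with an estimated correlation). Hba-a1, an alpha-globin gene, was at 359, 656 and 5737 CPM in wild-type replicates 1, 2 and 3 and at 117, 326 and 24.5 CPM in mutant replicates 1, 2 and 3. Hbb-b1, a beta-globin gene, was at 2875 CPM in wild-type replicate 3 and at 12.3 to 272 CPM elsewhere. Both globins share reads with near-identical copies, so the split between copies is uncertain. Meningeal fibroblast genes were lower in 14 of 15 members (median −2.30, camera adjusted p = 0.00180, and adjusted p = 0.983 with an estimated correlation). The collagen gene Col1a1 was at 592 CPM in wild-type replicate 3 and at 4.68 to 27.6 CPM elsewhere, and Col1a2 at 233 CPM there and at 0.826 to 21.1 CPM elsewhere. Without wild-type replicate 3 the meningeal call was lost (adjusted p = 0.278), as it was without mutant replicate 3 (0.0638), while the red blood cell list kept a call (0.00171). The median log2 difference without wild-type replicate 3 was −1.30 for red blood cell genes, with all 13 lower, and −0.69 for meningeal genes, with 9 lower and 6 higher. Without mutant replicate 2 the medians were −4.53 and −4.42. The meningeal median without mutant replicate 3 was −1.74, with 14 of 15 genes lower. Over either list alone 0 members passed, but 3 red blood cell and 5 meningeal genes did without mutant replicate 2, and 4 red blood cell genes without wild-type replicate 1.

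Immediate early and heat shock genes, which respond to handling within minutes to hours, were lower in 21 of 27 members (median −0.23, camera adjusted p = 0.0106, and adjusted p = 0.983 with an estimated correlation), with 0 past the test over the list alone. Their scores were −0.44, 0.56 and 1.21 in wild-type replicates 1, 2 and 3 and −0.64, 0.96 and −1.64 in mutant replicates 1, 2 and 3. The small heat shock gene Hspb1 was at 26.5 CPM in wild-type replicate 3 and at 0.0344 to 3.71 CPM elsewhere, and the phosphatase gene Dusp1 at 175 ± 52.1 and 130 ± 28.7 CPM (SD, n = 3 each). The call was lost without wild-type replicate 2 (adjusted p = 0.0828) or 3 (0.176), or without mutant replicate 1 (0.102) or 3 (0.257). In those fits the median was −0.20 without wild-type replicate 2, −0.058 without wild-type replicate 3, −0.16 without mutant replicate 1 and −0.062 without mutant replicate 3. It was −0.59 without wild-type replicate 1 and −0.97 without mutant replicate 2, where 5 members passed over the list alone.

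Among genes taken only for the smallest unadjusted p with separated groups, 6 in each direction, none passed edgeR over all genes. Higher with mutant PRPF6 were, besides Sox9, the adhesion molecule gene Vcam1 (log2 difference 1.89 ± 0.40, SE), the collagen gene Col22a1 (2.14 ± 0.45), the semaphorin gene Sema5b (1.00 ± 0.22), Pea15a (0.85 ± 0.18) and the calcium-binding protein gene Efhd2 (0.66 ± 0.14). Lower were, besides Snap25 and Syt4, the phosphate exporter gene Xpr1 (−1.21 ± 0.31), Ankrd12 (−0.86 ± 0.22), Kctd13, a cullin adaptor (−0.68 ± 0.19), and Pnisr, from counts partly shared with other genes (−0.52 ± 0.14). Of the higher genes, Sox9, Pea15a, Sema5b and Efhd2 passed DESeq2 (adjusted p from 0.0198 to 0.0288), as did Btg2, Nrarp and Qk from the lists (adjusted p = 0.0494 each). These calls come from the same libraries as the edgeR ranking and are not separate support. DESeq2 gave no adjusted p for 11213 genes, and 7 of 10 splits of the libraries gave at least 10 DESeq2 calls.

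The remaining lists did not pass camera. Adjusted p was 0.0796 for apoptosis, with 15 of 24 members higher, 0.544 for the integrated stress and unfolded protein responses and 0.397 for upper-layer neurons. It was 0.153 for cytosolic ribosomal proteins, 0.655 for nuclear oxidative phosphorylation, 0.397 for spliced snoRNA host transcripts and 0.952 for the primary cilium. Among other cell types it was 0.138 for microglia and macrophages, 0.386 for endothelial cells, 0.864 for pericytes and mural cells, 0.297 for the oligodendrocyte lineage and 0.952 for astrocytes. It was 0.544 for interneurons and ventral progenitors, 0.864 for Cajal-Retzius cells, 0.952 for choroid plexus and ependyma and 0.397 for the sex-linked list. In 8 lists the median, the mean or the score differed in sign from the test: S phase, migration, primary cilium, interneurons, microglia, pericytes, astrocytes and the sex-linked list. The microglia list, for example, tested lower with 17 of 20 members higher (median 0.51), and without mutant replicate 2 all 20 were lower (median −2.09), 9 of them past the test over the list alone.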

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

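The fits with the red blood cell or Y-linked score and the fit without both wild-type replicate 3 and mutant replicate 1 were chosen after the data were seen, and the fit with length and GC trends removed was added here later. edgeR called 0 genes in each alternative, with 307 to 1016 genes at an unadjusted p under 0.05, the most without mutant replicate 2, and limma-voom called 0. DESeq2 called 10 genes, 10 of them higher, and 12 at an adjusted p under 0.1. No list call held with an estimated correlation or in fry, each with 0 lists. Adjusted p with an estimated correlation and in fry was 0.721 and 0.687 for radial glia, 0.721 and 0.677 for p53 targets, 0.721 and 0.696 for neuronal maturation, 0.339 and 0.220 for Notch signalling and 0.766 and 0.827 for red blood cells. It was 0.983 and 0.968 for each of newborn neurons, regulatory splicing factors, immediate early genes and meningeal fibroblasts. DESeq2 size factors and the stricter filter kept the 9 calls.

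The replicate numbers were not taken to pair the libraries: the correlation of same-numbered libraries' deviations from their group means was 0.054, 0.061 and −0.26, and not every library correlated best with its own number. With the replicate block edgeR called 0 genes and camera 8 lists. The call lost was that of regulatory splicing factors (adjusted p = 0.0772), whose median log2 difference was −0.14 with and without the block. The other 8 list calls kept their side of the threshold. Members past the test over the list alone were 4 for radial glia, as without the block, and 0 for Notch signalling, intermediate progenitors and astrocytes, against 3, 1 and 1.

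With the red blood cell score 16 lists passed, 5 of them among the 9. Adjusted p was then 0.144 for neuronal maturation, 0.663 for meningeal fibroblasts and 0.218 for the red blood cells themselves, a list the covariate is made from. Directions turned for immediate early genes (0.348), intermediate progenitors (0.168), S phase (0.0107), G2 and M phase (0.235), the tri-snRNP (0.0852) and Dusp1 (log2 difference 0.021). Without both named libraries adjusted p was 0.153 for regulatory splicing factors, 0.344 for immediate early genes and 0.227 for meningeal fibroblasts, on fewer libraries. With length and GC trends removed 11 lists passed, regulatory splicing factors did not (0.385), and neuronal migration (0.959) and the centrosome (0.988) turned direction. The cause of the other shifts was not tested. Where an estimated correlation was also tried in an alternative, no list passed (lowest adjusted p = 0.295).

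Leaving out each library in turn gave 9 to 18 lists, the most without mutant replicate 2. Adjusted p ranged from 9.40e-12 to 0.00171 for radial glia, 1.55e-08 to 0.000748 for p53 targets, 4.15e-05 to 0.00458 for Notch signalling, 1.11e-06 to 0.0166 for neuronal maturation and 1.28e-07 to 0.00478 for red blood cells. Calls were lost in ranges of 0.000142 to 0.244 for newborn neurons, 0.00237 to 0.396 for regulatory splicing factors, 7.03e-05 to 0.257 for immediate early genes and 3.11e-05 to 0.278 for meningeal fibroblasts. The log2 difference of Prpf6 ranged from −0.16 to 0.067. Among lists without a call, adjusted p with turns of direction ranged from 0.0356 to 0.938 for the tri-snRNP, 0.323 to 0.948 for neuronal migration, 0.0166 to 0.979 for the centrosome, 0.00728 to 0.862 for S phase and 1.56e-07 to 0.592 for G2 and M phase. Of 17 further lists 11 passed in at least 1 alternative and 15 turned direction in at least 1. In the simulations, which changed 200 genes at once, most 2-fold changes were not detected at this depth and spread. The simulations do not measure detection of a change in 1 gene alone.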

Other observations

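Of the tests in this part, the splits of the libraries for DESeq2, the length and GC corrections and the intron relations were set before their result was seen, and the others were chosen after. The bars for reading them were also revised after the values were seen: a kept list call counts against an explanation as the whole cause only where the median log2 difference keeps more of its size than it loses (a bar set in advance for the length and GC scores), and a bar of a call with an estimated correlation was dropped because no list met it in the main fit. The stress test was likewise made to depend on the red blood cell covariate after its result was seen. Several libraries carried genes of particular cells or regions, whichever group they belonged to. Mutant replicate 2 had the highest microglia list score, 2.55, and Csf1r, the receptor microglia need to survive, was at 197 CPM there and at 6.34 to 67.2 CPM elsewhere. Mutant replicate 1 had the most Sp9, a gene of ventral forebrain progenitors (357 CPM, elsewhere 57.2 to 151 CPM), and the most Otx2 (144 CPM, elsewhere 17.2 to 46.0 CPM). In the same library the cortical neuron gene Tbr1 was lowest (61.7 CPM, elsewhere 143 to 265 CPM). Aldh1l1, a gene of astrocytes and some radial glia, was at 73.9 CPM in mutant replicate 1 and at 1.25 to 15.2 CPM elsewhere. It was the 1 member of the astrocyte list past edgeR's test adjusted over the list alone, a count that was 0 without mutant replicate 1 or any 1 wild-type replicate. The choroid plexus list, which holds Otx2, also scored highest in mutant replicate 1 (1.90). The lists of Sp9 and Aldh1l1 did not follow these genes: the interneuron and ventral progenitor score was highest in wild-type replicate 3 (1.15, mutant replicate 1 0.64), and the astrocyte score of mutant replicate 1, 0.46, was below those of wild-type replicates 2 and 3 and mutant replicate 2 (0.52, 1.18 and 0.54). The genes of this paragraph were named after their values were seen.

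Xist, the RNA of the inactive X chromosome, was at 240, 76.5 and 85.7 CPM in wild-type replicates 1, 2 and 3 and at 192, 1.93 and 2.65 CPM in mutant replicates 1, 2 and 3. The Y-linked Ddx3y was at 5.59, 52.0 and 36.7 CPM in the wild-type and at 3.12, 67.5 and 39.9 CPM in the mutant libraries. Wild-type replicates 2 and 3 thus carried both transcripts, mutant replicates 2 and 3 mainly Ddx3y, and wild-type replicate 1 and mutant replicate 1 mainly Xist. The genes DESeq2 called besides those named in the comparison were Ednrb, the growth factor receptor gene Fgfr3 (140 ± 32.8 and 264 ± 28.4 CPM, SD, n = 3 each) and Tspan18.

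With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 0 genes in edgeR and the highest of the others 0, so 10 of 10 splits gave as many. It gave 9 lists and the highest other 20, with 7 of 10 giving as many, and in DESeq2 10 genes and the highest other 289, again with 7 of 10. That highest split set wild-type replicate 1 and mutant replicates 1 and 3 against the other 3 libraries, and its many calls point to a structure of the samples that crosses the groups. The 3 libraries of its other side, wild-type replicates 2 and 3 and mutant replicate 2, were those with red blood cell scores above 0 and microglia scores above 0.

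One pattern is the higher radial glia and Notch lists with mutant PRPF6. Transcript length or GC bias is argued against by the radial glia list's call with both trends removed from each library (camera adjusted p = 2.54e-07). Blood and meningeal RNA in wild-type replicate 3 is argued against as the whole cause: without that library the radial glia call held (0.00171, median log2 difference 0.41 against 0.57), as did that of Notch signalling (0.00458, 0.50 against 0.47). It may still be part of the cause for radial glia, whose score difference fell from 0.56 to 0.35 (wild-type scores −0.24 and 0.093, mutant scores 0.25, 0.19 and 0.39), while that of Notch signalling went from 0.43 to 0.46. A difference in Y-linked transcripts as the whole cause is argued against by the fit with a Y-linked score. The median there was 0.55 for radial glia (2.53e-09) and 0.43 for Notch signalling (3.27e-05), while that of choroid plexus turned from 0.29 to −0.66. The Y-linked score leaves out Xist, which was higher in wild-type than in mutant replicates 2 and 3. The sex makeup of the libraries therefore stays open. The radial glia score difference was above that of any other split (0.49), as was that of Notch signalling (0.43 against 0.32), but 2 other splits gave the radial glia list a camera p of 1.21e-07 and 2.94e-07, against 2.54e-10. A shift toward radial glia is left open, whether from mutant PRPF6, wild-type PRPF6 or a chance difference in which cells were electroporated or sorted. Without a group given no PRPF6 plasmid, higher lists with mutant PRPF6 cannot be told from lower lists with wild-type PRPF6. With an estimated correlation neither list passed in any fit where it was tried.

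Another pattern is the higher p53 target list. Length or GC bias is argued against by a camera adjusted p of 3.03e-06 with both trends removed. Stress from dissociation and sorting should raise immediate early genes where p53 targets are highest. Of mutant replicates 1 and 3 the higher immediate early score was −0.64, below the lowest wild-type score of −0.44, but these scores were above 0 only in the 3 libraries with red blood cell scores above 0, and with the red blood cell score as covariate 18 of 27 of these genes were higher (adjusted p = 0.348), so stress stays open. A single library as the whole source is argued against by the 6 fits that left out a library, where the highest adjusted p was 0.000748 and the lowest median 0.46 (main 0.67), both without mutant replicate 3. With an estimated correlation adjusted p was 0.721 in all libraries and 0.492 to 0.978 in those fits, so the list call itself rests on the preset correlation. The score difference of 0.67 was close to those of 2 other splits (0.60 and 0.59), where the list's camera p was 0.000125 and 8.72e-07, and a response to mutant PRPF6 or to the plasmid dose, not given in the sources used here, was not tested.

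The last pattern weighed is the lower red blood cell and meningeal lists. Cells from outside the cortex in wild-type replicate 3 are a candidate source for the meningeal list, whose camera adjusted p was 0.278 without that library, although a GFP sort should remove most such cells. For the red blood cell list it stays open whether that library is the whole source: without it all 13 genes were lower and the adjusted p was 0.00171, but the median log2 difference went from −2.80 to −1.30, 46.6% of its size. The list's score difference kept more of its size, going from −2.86 to −1.95. Without that library Hba-a1 still ran from 24.5 CPM in mutant replicate 3 to 656 CPM in wild-type replicate 2. No biological explanation was tested for this pattern.

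Because PRPF6 acts in splicing, a hypothesis set before the test was that genes with more or longer introns would be lower with mutant PRPF6. Across 12844 genes with at least 1 intron, Spearman's rho of the log2 difference was 0.012 with intron number and −0.037 with total intron length, where genes are not independent replicates. As large a rho, in size, came from 9 of 10 splits for intron number (highest other 0.14) and 8 of 10 for intron length (highest other 0.14), so neither relation stood out. Gene counts cannot show retained introns or exon choice. With length and GC trends removed, the regulatory splicing factor list had a score difference of −0.041, against −0.15 before, and a camera adjusted p of 0.385. In the same fit 3 lists without a call passed: deep-layer neurons (0.0103) and microglia (0.0272) as lower, and G2 and M phase (0.0256) as higher.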
